A study of Equus caballus with 24 samples.

How the data were processed

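Reduced representation bisulfite sequencing (RRBS) reads the methylation of cytosines in the CpG-rich part of the genome that a restriction digest and size selection retain. Per the labels' protocols, DNA from frozen tissue was made into libraries with the Ovation RRBS Methyl-Seq kit, and 24 libraries in 2 pools were sequenced on a NextSeq 500 as single-end reads of 75 bp. The labels do not say which library was in which pool, so the pool could not enter any comparison. Per the submitters' processing notes, FastQC, BSMAP (a bisulfite read aligner) and methylKit (an R package for methylation calls) were used, with the genome build EquCab3.0. Versions, trimming and mapping settings are not given in the sources used here.

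Per the file headers, 23 of the 24 deposited tables hold methylKit call columns, with the coverage of a cytosine as a read count and its methylated and unmethylated shares as a percent. The deposited table of skin replicate 1 instead has the columns of a BSMAP methylation report, with read counts on both strands and the methylated share as a fraction. All tables have a minimum of 5 reads per cytosine and strand. The table with a context column holds CpG cytosines only, and the cytosines of the other tables were taken as CpGs. In the library held in both layouts, the deposited percent is a share of reads after an adjustment for apparent C-to-T variants, while the coverage is the unadjusted count, and the adjustment changed the effective depth at 1.77% of cytosines. In each sample, at 0.863% to 1.56% of cytosines with 10 to 50 reads, the share times the coverage missed a whole number by more than the rounding of the share allows (0.0005 as a fraction, times the coverage). The same adjustment was assumed for the other libraries. Methylated reads were taken as the coverage times the deposited share, rounded to whole reads.

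Skin replicates 1 and 2 had the same coverage and the same share, within a fraction of 0.00051, at all 3622034 cytosines. They were counted as 1 library, called skin replicate 2 here, so that 12 sarcoid and 11 skin libraries entered each comparison. The labels name no animals, so p-values measure only the spread between these samples. Replicate numbers follow the accession order and only name a library.

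The 2 strands of a CpG were merged. A CpG counted in a library at 10 or more reads and, on autosomes and X, at or below that library's 99.9th percentile of autosomal coverage. It was testable when it counted in at least 10 libraries of each group. No upper coverage limit was set on unplaced scaffolds or on the mitochondrion. Autosomes 1 to 31 entered the main comparisons. Tiles were non-overlapping windows of 1000 bp with 3 or more testable CpGs, with reads summed over those CpGs, and were tested with values in at least 10 libraries of each group. The median depth per testable CpG ranged from 20 to 49 reads over libraries, and the median depth per tile from 82 to 218 reads. RRBS reads without molecular identifiers are not independent molecules.

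Sites and tiles were tested with a quasi-binomial model of methylated and unmethylated reads on the group, the model of methylKit with its correction for overdispersion and an F test. P-values were adjusted with the Benjamini-Hochberg method over the features tested. A feature was called when its adjusted p was below 0.05, its group means of the library percentages differed by at least 10 percentage points, and the model gave the same direction. Gained and lost mean higher and lower in sarcoid than in skin. Values per library were compared with two-sided permutation tests of 100000 resamples of the difference of group means, or with exact permutation tests where a group had fewer than 10 values. The exact tests, the classes by level in skin and the split by the range of X-linked CpGs were not planned. The other choices, and the rule for named regions, were fixed before the data were examined. The rule takes the 5 called tiles and the 2 called CpGs with the largest gain, and as many with the largest loss, where at least 10 sarcoids lie on the same side of the skin median. Counts of sarcoids on that side are therefore no separate support for a named region.

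Promoters, gene lists, cell type markers, CpG islands and gene names needed an annotation of the build of the tables and were not analysed here. In place of annotated contexts, CpGs were classed by the number of CpGs seen in any library within a window of 200 bp around them, as sparse (fewer than 8), intermediate (8 to 15) or dense (16 or more). These classes, the windows of 1 Mb and the runs of tiles were chosen after the data were seen. Coordinates are positions as the tables give them.

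The model was tested on simulated reads with the real depths and overdispersion. Among 68360 simulated tiles, 67% of 100 tiles changed by 25 points and 5% of 100 changed by 10 points were recovered, with 2 unchanged tiles called. Among 461337 simulated sites, 7% of 100 sites changed by 25 points and 1% of 100 changed by 10 points were recovered, with 1 unchanged site called. The limma model recovered 74% of the tiles changed by 25 points and 1% of those changed by 10 points. So few changed features make the adjusted threshold stricter than in the real data, where 83426 sites had an adjusted p below 0.05. The recovered shares therefore do not give the power of the real comparison. Unchanged tiles had p below 0.05 in 5.82% of cases with the quasi-binomial model and in 4.89% with limma.

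Alternatives covered the coverage limits, the number of libraries required, the weighting, the X chromosome, strands, overdispersion, thresholds, limma on M values (log2 of methylated reads plus 1 over unmethylated reads plus 1), and leaving out each library. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, R 4.3.3 and limma 3.58.1 were used.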

Results

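CpG methylation was measured by RRBS in tissue of equine sarcoids, locally invasive skin tumours of horses that are associated with bovine papillomavirus, and in horse skin. The labels give 12 sarcoid and 12 skin samples, and 2 of the skin samples held the same library, which leaves 12 sarcoid and 11 skin libraries. The total coverage of CpG cytosines ranged from 53601292 reads in skin replicate 3 to 105867083 reads in skin replicate 11. Between 39.2% and 58.0% of this coverage lay on scaffolds not placed on a chromosome. On the autosomes, 461337 CpGs and 68360 tiles of 1 kb were testable. The labels give no sex, and the number of X-linked CpGs per 100 autosomal CpGs fell into 2 ranges, 1.89 to 2.12 and 3.06 to 3.32. The upper range held 3 of the 12 sarcoids and 8 of the 11 skin libraries, so the groups were unbalanced in this measure.

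The first comparison asked whether the overall methylation of sarcoid differs from that of skin. Sarcoids had a lower mean level, 70.2% ± 2.63 (SD, n = 12) against 72.1% ± 0.662 (SD, n = 11) in skin, a difference of -1.89 percentage points (permutation test, two-sided, p = 0.0310). In 8 of the 12 sarcoids the mean lay below every skin library, and in 2, replicates 2 and 8, it lay above every one, at 74.31% and 73.9985%. The 8 include replicates 9, 10, 11 and 12, which form 2 pairs with shared variant-like profiles (described below) and may not be independent. The lowest sarcoid was replicate 11 at 65.8%, while skin ranged from 70.97% to 73.45%. The call was not stable. The difference was -1.71 points without sarcoid replicate 6, -1.76 without 7, -1.70 without 9, -1.49 without 11 and -1.71 without 12, and -1.75 without skin replicate 7, with p between 0.0505 and 0.0567 in these 6 cases. It was -1.60 points with 1 library per variant-like profile, sarcoid replicates 10 and 12 left out (permutation p = 0.0793), and -1.57 points with each read weighted equally (permutation p = 0.0595). Without sarcoid replicates 2 and 8, a choice made after their values were seen, it was -2.69 points (permutation p = 0.00041), and -3.08 points at the sparse CpGs described next (adjusted p = 0.00110). Within the lower range of X-linked CpGs the difference was -1.77 points (9 sarcoids against 3 skin libraries, exact permutation test, p = 0.30), and within the upper range it was -1.01 points (3 against 8, exact permutation test, p = 0.121).

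Lower methylation was found where CpGs are sparse and was not detected where they are dense. At 360909 sparse CpGs the mean was 72.9% ± 2.84 (SD, n = 12) in sarcoid and 75.1% ± 0.726 (SD, n = 11) in skin (difference -2.24 points, permutation p = 0.0191, adjusted p = 0.0477 over 5 classes). At 89225 CpGs of intermediate density the values were 63.4% ± 1.94 and 64.2% ± 0.516 (difference -0.777 points, permutation p = 0.213, adjusted p = 0.355). At 11203 dense CpGs, the class nearest to CpG islands, both groups had 37.1% to 37.2%, with SDs of 1.44 and 0.989 (permutation p = 0.924, adjusted p = 0.924). The differences between these classes were not tested. On X the means were 72.8% ± 2.19 and 73.5% ± 1.16 (permutation p = 0.373, adjusted p = 0.466). On unplaced scaffolds sarcoid was lower at 86.3% ± 0.842 against 87.2% ± 0.426 (difference -0.821 points, permutation p = 0.00740, adjusted p = 0.0370). The sparse-CpG call held without any 1 of sarcoid replicates 2, 4, 5 and 8 and skin replicate 8, and ended without any 1 of the other 18 libraries (-1.79 to -2.32 points, lowest adjusted p 0.0529). The scaffold call ended without any 1 of sarcoid replicates 3, 6, 9, 10, 11 and 12 and skin replicates 2, 4, 7, 9, 10 and 11 (-0.681 to -0.833 points, lowest adjusted p 0.0509). Neither held with 1 library per variant-like profile (-1.92 points, adjusted p = 0.126, and -0.675 points, adjusted p = 0.120), nor did the sparse-CpG call at a minimum of 5 reads (-2.22 points, adjusted p = 0.0614).

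**Figure D1:**
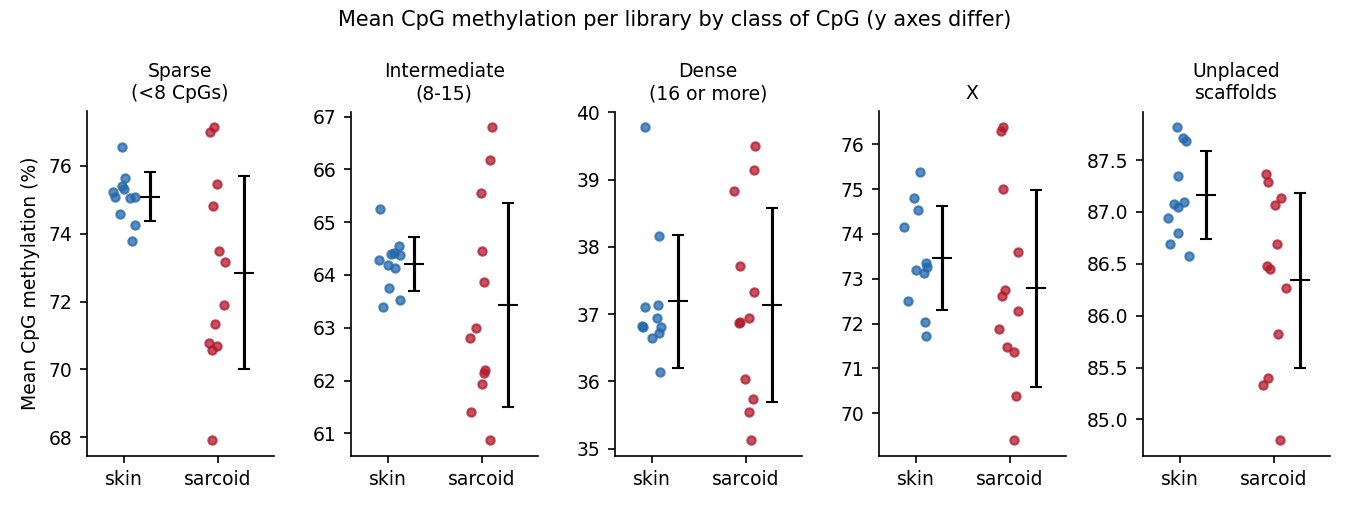
Mean CpG methylation (percent) of each library for 3 classes of autosomal CpG density, X and unplaced scaffolds; points are the 12 sarcoid and 11 skin libraries, black marks are means with SD, and the y axes differ and do not start at 0. Sarcoids spread further than skin at sparse CpGs, from 67.9% to 77.1% against 73.8% to 76.6%.

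The second comparison asked which single CpGs differ. Losses outnumbered gains: 45198 CpGs, 9.80% of those tested, were lost in sarcoid, and 24424, 5.29%, were gained. This balance did not hold in limma on the 10 libraries whose title numbers occur in both groups, with 3872 CpGs gained and 3555 lost. The median loss was -18.9 points and the median gain 21.2 points. Sparse CpGs had 11.2% lost and 5.71% gained, CpGs of intermediate density 5.18% and 4.14%, and dense CpGs 1.67% and 1.22%. At the stricter limits of adjusted p below 0.01 and 25 points, 8765 CpGs were lost and 7198 gained.

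The mean change was also computed by the level in skin, which was not planned. To keep chance values out of the classes, CpGs were classed by their mean in 5 skin libraries, and sarcoids were compared with the 6 other skin libraries. CpGs at 70% to 90% in skin had 77.3% ± 3.24 (SD, n = 12) in sarcoid against 81.7% ± 0.851 (SD, n = 6) in skin (exact permutation p = 0.00291, adjusted p = 0.00727 over 5 classes). CpGs above 90% had 91.8% ± 1.13 against 94.1% ± 0.313, with an exact permutation p of 0.000108, the smallest this design can give (adjusted p = 0.000539). CpGs at 10% to 30% in skin were higher in sarcoid, 24.5% ± 4.51 against 20.5% ± 1.18 (exact permutation p = 0.0274, adjusted p = 0.0456). CpGs at 30% to 70% had 55.3% ± 4.81 against 54.1% ± 1.12 (exact permutation p = 0.579), and CpGs under 10% had 3.53% ± 0.721 against 3.08% ± 0.238 (exact permutation p = 0.162). Levels near 0% can hardly fall and levels near 100% can hardly rise, so the direction in the outer classes is bounded by the scale. These tests counted all 12 sarcoids as independent and were not repeated with 1 library per variant-like profile.

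**Figure D2:**
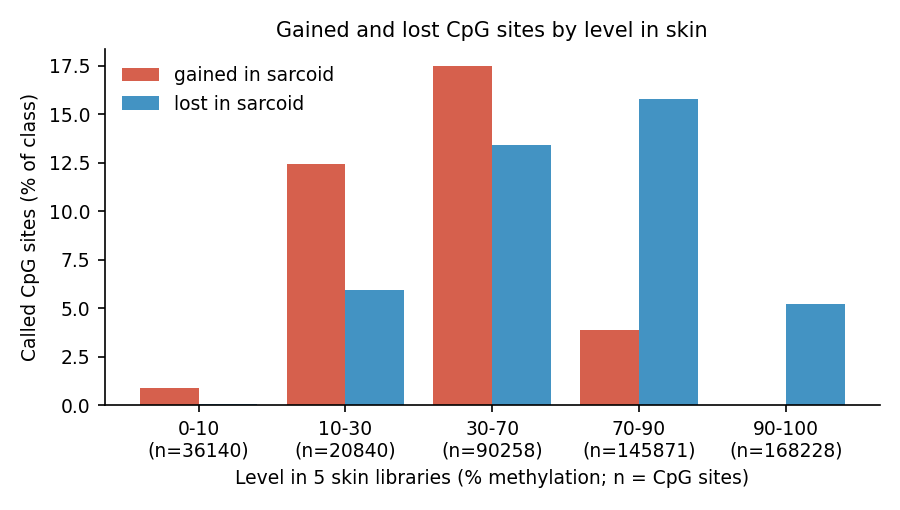
Share of CpG sites gained or lost in sarcoid (percent of the class), by the mean level in 5 skin libraries; the calls themselves used all 11 skin libraries. Losses took 15.8% of CpGs at 70% to 90% in skin and 5.25% above 90%, and at 30% to 70% gains took 17.5% and losses 13.4%; a call needs 10 points, so CpGs under 10% can hardly be called lost, nor those above 90% gained.

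The 2 CpGs with the largest gains were at positions 58328075 of chromosome 4 and 52299729 of chromosome 5. The first had 85.3% ± 16.6 (SD, n = 11) in sarcoid and 19.1% ± 5.33 (SD, n = 10) in skin, at a median of 21 reads per library (adjusted p = 1.2e-05, higher than the skin median in 11 of 11 sarcoids). The second had 86.7% ± 13.6 (SD, n = 11) and 23.02% ± 30.4 (SD, n = 10), at 29 reads (adjusted p = 0.00042, 11 of 11 sarcoids), and its skin libraries ranged from 0% to 80%. The 2 largest losses were at position 3450329 of chromosome 4 and position 33119082 of chromosome 21. The second of these had 19.6% ± 14.7 (SD, n = 11) in sarcoid and 81.8% ± 12.8 (SD, n = 10) in skin, at 26 reads (adjusted p = 3.7e-05, 11 of 11 sarcoids). The CpG at 3450329 had 8.53% ± 19.7 (SD, n = 12) and 72.3% ± 33.0 (SD, n = 11), at 61 reads (adjusted p = 0.00297, 12 of 12 sarcoids). There the libraries lay near 0%, near 50% or above 90%, a pattern that a C-to-T variant also gives. Both this CpG and that at 52299729 were left out when 1674 variant-like CpGs were removed as an alternative. That set is larger than the 228 variant-like CpGs compared between libraries below, whose definition neither CpG meets. Neither was tested once the 1674 were removed, so a variant remains possible at both.

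The third comparison asked which 1 kb regions differ. Of 68360 tiles, 7290 (10.7%) were lost and 4241 (6.20%) gained in sarcoid, with a median loss of -15.6 points and a median gain of 17.5 points. In 306 of the 56086 tiles covered in every library all sarcoids lay above all skin libraries, and in 374 all lay below. Chance gives 0.083 such tiles for groups of 12 and 11 independent libraries. These counts were not repeated with 1 library per variant-like profile. With M values centred on each library's median, which removes a shift of -0.205 (log2) between the groups, limma called 5500 tiles lost and 4816 gained, against 6946 and 4338 without centring. Centring moves the balance of losses and gains toward equality by construction, so it does not test that balance. With the 2 sarcoid libraries left out that share variant-like CpGs with another sarcoid, 84.9% of the called tiles were still called.

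The tile with the largest gain was on chromosome 4 (EquCab3.0), from 58328001 to 58329000. Its 4 CpGs had 80.5% ± 16.5 (SD, n = 12) in sarcoid and 20.5% ± 6.79 (SD, n = 11) in skin, a gain of 59.96 points (adjusted p = 1.7e-06, 12 of 12 sarcoids, median 78 reads per library). The tile from 58313001 to 58314000 gained 53.3 points (72.3% ± 21.7 against 19.04% ± 5.48, adjusted p = 5.8e-05, 12 of 12 sarcoids, 222 reads). The tile from 58341001 to 58342000 gained 51.6 points (75.6% ± 19.2 in 11 sarcoids against 24.0% ± 11.2, adjusted p = 1.9e-05, 11 of 11 sarcoids, 82 reads). These tiles lie in 1 region, described here after its values were seen. Between 58313001 and 58357000 on chromosome 4, all 9 tiles tested were gained, by 20.9 to 59.96 points, while 5.29% of tiles on the whole chromosome were gained. None of the next 3 tiles tested was called (differences -17.9, 4.75 and -2.12 points), and from 58370001 to 58376000 4 of the 5 tiles tested were lost, by -21.3 to -28.4 points. The largest sarcoid SD in the gained stretch was 26.4 points, in the tile starting at 58356001, so the sarcoids differed in how far they rose.

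**Figure D3:**
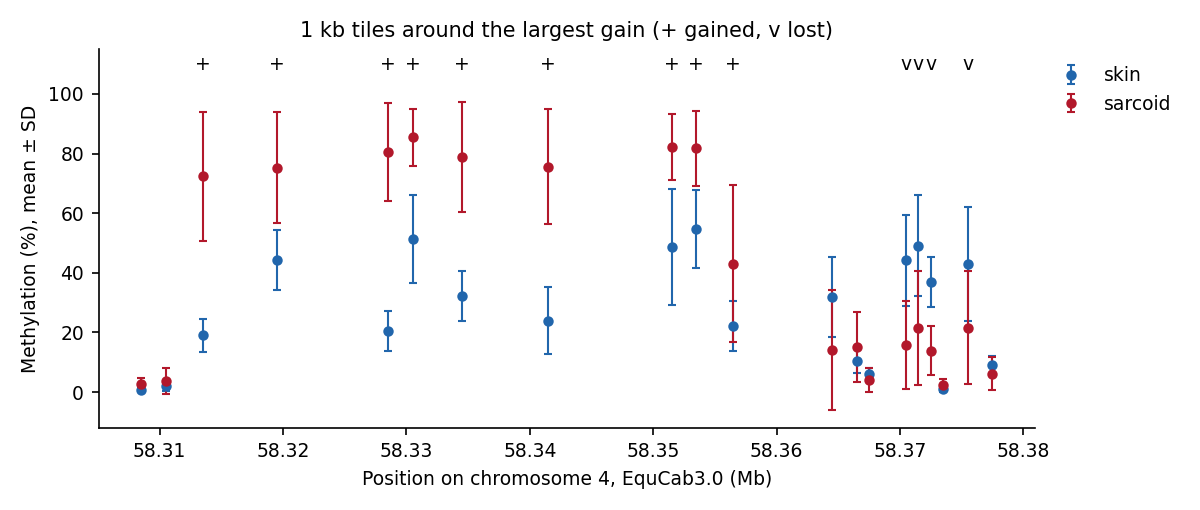
Methylation (percent, mean with SD over libraries) of the 1 kb tiles within 50 kb of the tile with the largest gain, by position on chromosome 4 in EquCab3.0; plus signs mark gained and v marks lost tiles. The 9 gained tiles are followed by 3 tiles without a call and then a stretch with 4 lost tiles.

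The 2 other named gains were on chromosomes 6 and 9. The tile from 41514001 to 41515000 of chromosome 6 rose from 37.8% ± 12.0 (SD, n = 11) in skin to 86.5% ± 12.2 (SD, n = 12) in sarcoid (adjusted p = 1.0e-05, 279 reads). The tile from 84681001 to 84682000 of chromosome 9 rose from 25.2% ± 11.8 to 73.9986% ± 18.2 (adjusted p = 2.9e-05, 94 reads). Both were higher in 12 of 12 sarcoids.

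The 5 largest losses lay on 5 chromosomes. The tile from 33119001 to 33120000 of chromosome 21 had 24.3% ± 10.9 (SD, n = 11) in sarcoid and 79.5% ± 7.52 (SD, n = 10) in skin (difference -55.2 points, adjusted p = 1.8e-06, 103 reads), and it holds the named CpG on that chromosome. The tile from 2246001 to 2247000 of chromosome 13 had 22.5% ± 10.9 against 75.0% ± 9.64 (-52.4 points, adjusted p = 1.6e-06, 96 reads). The tile from 57623001 to 57624000 of chromosome 6 had 30.1% ± 25.7 (SD, n = 10) against 82.0% ± 7.05 (-51.9 points, adjusted p = 9.4e-05, 51 reads), with sarcoids from 1.59% to 69.0%. The tile from 52112001 to 52113000 of chromosome 1 had 24.1% ± 14.7 against 75.6% ± 5.08 (-51.4 points, adjusted p = 2.3e-06, 83 reads). The tile from 93412001 to 93413000 of chromosome 5 had 21.03% ± 10.8 (SD, n = 10) against 72.1% ± 9.04 (-51.0 points, adjusted p = 1.7e-06, 57 reads). In all 5 tiles each sarcoid with a value lay below the skin median, which the naming rule required of at least 10 sarcoids.

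Called tiles mostly stood alone, at a coverage that leaves many adjoining tiles untested. Called tiles of 1 direction that lay within 5 kb of each other were joined, which left 6772 separate losses and 4037 separate gains. Of these, 65 losses and 22 gains spanned 3 or more tiles. The longest loss held 6 of 6 tested tiles between 10968001 and 10979000 of chromosome 8, with 42.9% ± 10.03 (SD, n = 12) in sarcoid and 67.9% ± 6.09 (SD, n = 11) in skin. Losses with 5 tiles each lay between 33776001 and 33785000 of chromosome 3 (41.1% ± 8.997 against 59.5% ± 3.25) and between 1978001 and 1991000 of chromosome 13 (61.7% ± 8.51 against 78.1% ± 1.93). The longest gains held 4 tiles each, between 20840001 and 20845000 of chromosome 8 (48.4% ± 21.9 against 25.6% ± 6.43) and between 37418001 and 37428000 of chromosome 15 (62.1% ± 4.20 against 51.8% ± 5.02).

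The last comparison asked whether sarcoids differ from each other more than skin samples do. They did: the mean absolute distance of a library from the mean of the others of its group, over 56086 tiles, was 6.65 points ± 1.11 (SD, n = 12) in sarcoid and 4.14 points ± 0.523 (SD, n = 11) in skin (permutation test, two-sided, p = 2.0e-05). Each of the 12 sarcoids, from 4.98 to 8.28 points, lay above the highest skin library at 4.93 points. On M values 9 of the 12 did (lowest sarcoid 0.544, highest skin library 0.565), so the complete separation depends on the scale. The permutation shuffled the labels over fixed distances and did not recompute them. Distances within a group depend on each other, so this p is only approximate. The test was not repeated with 1 library per variant-like profile. The first principal component of the tiles took 33.4% of the variance and separated the groups, with skin scores from 3.35 to 6.28 and sarcoid scores from -9.02 to 2.07. Sarcoid replicates 1, 2, 5 and 8 were the nearest to skin on this component. Replicates 2 and 8 stood apart on the second component, which took 14.8%, with scores of -8.95 and -7.82.

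**Figure D4:**
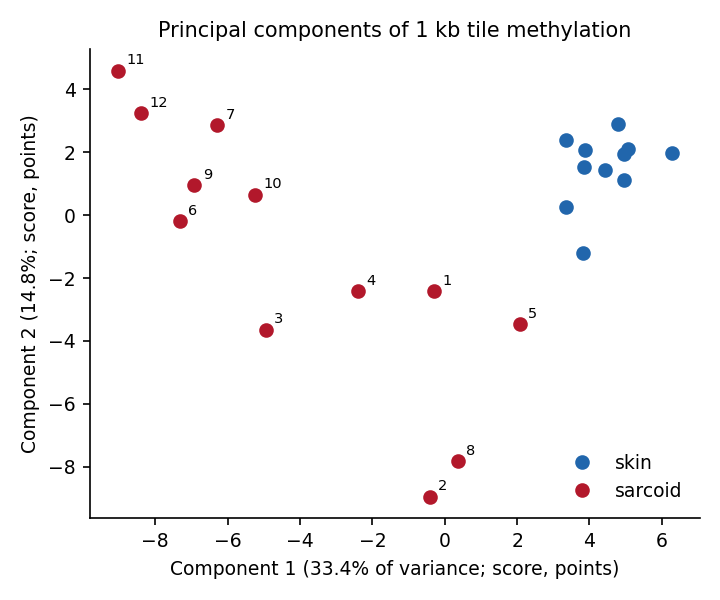
Scores of the 23 libraries on the first 2 principal components of methylation in 56086 tiles, in points; the axis labels give the share of variance, and numbers mark sarcoid replicates. Skin libraries form a tight group, while sarcoids extend along both components.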

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

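The tests of incomplete conversion and over-conversion, of the X share, of repeated animals and of variant-like CpGs were chosen after the data were seen, and the interval bounds for cell shares and depth were added after their correlations were seen. CpGs on the X chromosome and on unplaced scaffolds took no part in the site and tile counts of the report, and both held sites higher in sarcoid than in the skin controls. On X, 241 CpGs were gained and 348 lost of 11470 tested, in groups unbalanced in the X share. Within the upper range of X-linked CpGs the median ratio of the difference to the whole difference over these sites was 0.638, within the lower range 1.09, and with both ranges combined 0.891. The upper range held 3 sarcoids and the lower range 3 skin libraries. The sites were called in these same libraries, which favours ratios near 1. The values therefore argue only weakly against an unequal sex ratio as the whole cause. On unplaced scaffolds, 242 were gained and 2711 lost of 362184 tested. For each of these sets 1 of the 101 splits of the 23 libraries, the real one, called as many sites, and the highest count of the other splits was 0. This argues against chance, as far as this number of splits can show and with all sarcoids taken as independent.

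The 69622 called CpGs and 11531 called tiles were weighed against technical explanations. Chance is argued against: among 101 splits only the real one called as many sites or tiles, and the highest counts of the other splits were 1 site and 10 tiles. A share below 1 of 101 cannot be shown with these splits, which also treated all 12 sarcoids as independent. Unequally incomplete conversion was tested on 49 mitochondrial CpGs, taken as unmethylated: their level was 0.333 points higher in sarcoid (95% bootstrap interval -0.686 to 1.29), which excludes the genome-wide difference of -1.89. Over-conversion of methylated cytosines would lower CpGs in proportion to their level, but the relative loss above 90% in skin was 0.446 times that at 70% to 90% (95% bootstrap interval 0.398 to 0.560), which argues against it as the whole cause. The X share as a covariate argues against an unequal sex ratio as the whole cause. With it, the median ratio of adjusted to unadjusted limma effects over called tiles was 0.935. It left 5330 tiles lost and 4034 gained in limma, against 6946 and 4338 without it, and kept 78.2% of the called tiles against 94.0%. Within the upper range of X-linked CpGs the median differences at gained and lost tiles were 13.8 and -11.6 points. Within the lower range they were 20.6 and -17.0 points, so a partial contribution is not excluded. Repeated animals as the whole cause are argued against too, since 84.9% of the tile calls were still made with 1 library per variant-like profile. The pools of libraries and the cell types of tumour and skin tissue, as well as the tumour itself, were not told apart here and remain open.

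In 2 pairs of sarcoids, replicates 9 and 10 and replicates 11 and 12, the levels at variant-like CpGs (low, middle and high levels in both groups) correlated at 0.973 over 199 CpGs and 0.955 over 225, of 228 such CpGs, while the highest of the other 251 pairs of libraries had 0.241. This correlation is across CpGs, which are not independent replicates. These 228 CpGs are a smaller set than the 1674 variant-like CpGs of the alternative that removes such sites. A library entered under 2 names is argued against: its differences would be sampling noise, unrelated between the strands of a CpG, but they correlated at 0.411 (95% bootstrap interval 0.389 to 0.431) over 9634 CpGs in the first pair and at 0.691 (0.681 to 0.7002) over 21011 in the second. This test was chosen after the data were seen and replaces a planned Fisher's exact test of reads summed over tiles, which counts a read once per CpG. Each pair may come from 1 animal, as 2 tumours or 2 samples of 1 tumour, which remains a hypothesis.

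Sarcoids lay at different distances from skin. At tiles called without the sarcoid in question, the mean loss ranged from 4.85 points in replicate 5 to 25.6 points in replicate 11, and the mean gain from 11.4 points in replicate 5 to 24.4 points in replicate 2. Differently incomplete conversion is argued against, since the mitochondrial level, taken as unmethylated, ranged over sarcoids by 4.52 points and the mean loss by 20.8 points, and different over-conversion is argued against by the range of 2.56 points on unplaced scaffolds, which over-conversion would also lower. Different shares of skin-like cells could set both measures, but no joint rise of loss and gain was detectable over the 12 sarcoids (Pearson r = 0.108, permutation p = 0.738, adjusted p = 0.775; Spearman rho = -0.028, permutation p = 0.940, adjusted p = 0.940; r = -0.157 without the 2 sarcoids farthest from the median loss), and a bootstrap interval of r from -0.785 to 0.782 leaves this open. Library depth remains open too (Spearman rho = 0.133, permutation p = 0.681, adjusted p = 0.908; Pearson r = 0.127, permutation p = 0.702, adjusted p = 0.775; r = -0.272 without the 2 farthest sarcoids), and of the 4 relations in this family the others were mean methylation and distance, of which loss is a part (Pearson r = -0.662, permutation p = 0.0176, adjusted p = 0.0703; Spearman rho = -0.797, permutation p = 0.00292, adjusted p = 0.0117; r = -0.783 without the 2 farthest), and mitochondrial level and distance (Pearson r = -0.0885, permutation p = 0.775, adjusted p = 0.775; Spearman rho = -0.308, permutation p = 0.331, adjusted p = 0.661; r = -0.360 without the 2 farthest).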

How the results depend on the processing

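The settings that count 1 library per variant-like profile, leave out sarcoid replicates 2 and 8, count the identical skin tables as 2 samples, add the X share or remove variant-like sites were chosen after the data were seen. Leaving out 1 library at a time, the genome-wide difference ranged from -2.27 to -1.49 points, the sparse class from -2.63 to -1.79, the intermediate class from -1.08 to -0.545, X from -1.0 to -0.366, scaffolds from -0.914 to -0.681, and the dense class from -0.263 to 0.210. Gained sites then ranged from 21761 to 24932, lost sites from 38048 to 49104, gained tiles from 3993 to 4383 and lost tiles from 6337 to 8113. The genome-wide call ended with each read weighted equally (-1.57, p = 0.0595) and with 1 library per profile (-1.60, p = 0.0793); over the 10 alternatives other than leaving out 1 library, p ranged from 0.00041 to 0.0793. The cause was not tested. The sparse call ended at a minimum of 5 reads (-2.22, adjusted p = 0.0614) and with 1 library per profile (-1.92, adjusted p = 0.126), as did the scaffold call (-0.675, adjusted p = 0.120), where fewer sarcoids entered. Without replicates 2 and 8 the intermediate class (-1.39, adjusted p = 0.0135) and X (-1.38, adjusted p = 0.0407) passed. The dense difference, never called, was 0.222 at 5 reads, 0.0215 at 20 reads and 0.118 with 1 library per profile, and -0.485 without replicates 2 and 8.

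These settings moved counts by over 1.5 times. Some also changed the number tested, 461337 sites and 68360 tiles in the main run. At a minimum of 5 reads, 38493 of 932060 sites were gained, and 8325 of 140311 tiles were gained and 14568 lost. At 20 reads, 12343 of 212753 sites were gained and 23966 lost, and 1901 of 29484 tiles gained and 3078 lost. With 5 CpGs per tile, 1300 of 23632 tiles were gained and 1897 lost. Without overdispersion 39539 sites were gained and 73872 lost. At adjusted p below 0.01 and 25 points, 7198 sites were gained and 8765 lost, and 794 tiles gained and 950 lost. With no minimum difference 14496 tiles were lost. The 10 named tiles and 4 named CpGs kept their call in 387 of 387 and 146 of 146 values under the alternatives that tested them, and the 2 CpGs at 3450329 and 52299729 were not tested with variant-like sites removed. These tiles and CpGs were named for their large differences in the same data. Some settings, such as no minimum difference, could not end their calls, so these counts are weak support. The spread between samples was larger in sarcoid over CpGs and on M values too, though on M values 9 of 12 sarcoids lay above every skin library.

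Title numbers shared by both groups did not pair the libraries: over variant-like CpGs the 5 same-numbered pairs correlated at -0.0329 to 0.0516. The 2 sarcoid pairs with shared profiles had 0.955 and 0.973. Deviations over tiles correlated at 0.0244 to 0.0582 in the same-numbered pairs. Those deviations do not measure shared profiles, as sarcoid replicates 2 and 8 reached 0.551 there and -0.108 over variant-like CpGs. On these 10 libraries limma called 969 tiles gained and 1091 lost, and 3872 sites gained and 3555 lost of 366618, so more sites were gained than lost there. With the number as a replicate block it called 823 and 848 tiles, and 4176 and 3983 sites. Alternatives for promoters and gene lists were not run, nor was the removal of C/T variants by opposite-strand counts, which 1 library carries. At 20 to 49 reads per CpG, changes of 10 points in single CpGs were rarely recovered among simulated sites with few true changes.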

Other observations

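The direction of the difference was the same on all autosomes. On each of the 31 autosomes the mean was lower in sarcoid, from -1.30 points on chromosome 23 to -2.75 points on chromosome 21, and more tiles were lost than gained. Chromosomes of the same libraries are not independent, so the shared direction is no separate support for the genome-wide difference, whose call was not stable. No chromosome passed on its own (adjusted p from 0.0606 to 0.103 over 31 permutation tests). Chromosome 12 had the highest share of lost tiles, 13.6%, and chromosome 22 the highest share of gained tiles, 8.12%.

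In windows of 1 Mb over sparse CpGs, 1081 of 2260 windows were lower and 78 higher in sarcoid at an adjusted p below 0.05. These counts carry no minimum difference, unlike the calls of sites and tiles. Most differences were small: the median over the windows was -1.997 points, and 4 windows were lower and 1 higher by 10 points. The lowest window, from 61000001 to 62000000 of chromosome 18, had 62.5% ± 3.99 (SD, n = 12) in sarcoid and 73.8% ± 2.06 (SD, n = 11) in skin over 55 CpGs, with all 12 sarcoids below every skin library. The window from 19000001 to 20000000 of chromosome 26 had 76.8% ± 5.24 against 88.1% ± 1.96 over 34 CpGs. The window with the largest gain, from 29000001 to 30000000 of chromosome 19, had 80.8% ± 3.88 against 70.5% ± 3.04 over 62 CpGs. Of the 101 splits, 2, the real one included, passed the threshold in as many windows as the 1159 of the real one, and 1 other split had 1227.

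A hypothesis was tested that losses at sparse CpGs fall in large domains. Differences of 2 random sets of the tiles of each window correlated at r = 0.414 over windows, which are not independent replicates. Other splits of the libraries reached 0.538, and 16 of the 101 splits, the real one included, gave as high a correlation. Regional variation between libraries may therefore be as strong as that between the groups, and the domain hypothesis found no support specific to sarcoid.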
